A study of Mus musculus with 53 samples.

How the data were processed

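RNA was measured in 48 single-cell libraries: 22 of T1 pre-HSCs sorted from E11 embryos and 26 of adult HSCs sorted from bone marrow. According to the labels' protocols, deformed cells were discarded, each cell was moved by mouth pipette into lysis buffer holding ERCC spike-in RNA, and the T1 pre-HSC libraries were made with a template-switching method and the adult libraries with a poly(A)-based method. The 5 methylation libraries were not analysed here.

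The deposited table of the T1 pre-HSCs holds RPKM, read density scaled to transcript length and to the mapped reads of the cell, with 1 column per cell and 14833 genes. It was made with Cufflinks 2.1.0 on build mm10, per the submitters' processing notes; the aligner, the annotation and the treatment of reads that map to several places are not given in the sources used here. RPKM divides by gene length and by each cell's total, so a high share of a few genes in a cell lowers all its other values, and paralogues can trade reads. The per-cell totals of the listed genes were 865404 to 1129740 in KO cells and 909372 to 1085360 in wildtype cells. These values are estimates from which whole reads cannot be recovered, so depth and counting error per gene are unknown. An exact 0 can be a failed estimate, and such genes are called listed at 0. The table deposited for the adult HSCs does not name its unit. It was treated as FPKM, the same measure for fragments, because the submitters' processing notes name Cufflinks. The smallest value above 0 was 0.100, which does not settle the unit. It lists 6910 rows, and 95.4% of the 2541 rows that match a gene of the reference annotation by name are long non-coding RNAs there. There, 2 columns carry the same cell name and were not used, which leaves 25 of 26 cells. The tables were never tested against each other.

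Columns were assigned to samples by the cell numbers in their names, and groups were taken from the sample labels. No label names an embryo, litter or sort, so each group was treated as 1 sample, with no p-value, standard error or count of changed genes. The main value per gene is the difference of mean log2(RPKM + 1) over cells, KO minus wildtype, with a pseudocount of 1, which understates the change of low genes. Genes had to reach 1 RPKM in at least 50% of the cells of either group, which left 3867. A difference counted as large at 1 or more in size, a rule of size and not a test. Shares of cells at 1 RPKM or more carry exact Clopper-Pearson 95% intervals. The blank value of Etv6 in KO cell 5 was left out. For each gene list, the median difference of its compared members was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart at a percentile of 2.5 or less or 97.5 or more and needed 5 members. Marker lists of other cell types used all listed members without the filter. Spearman correlations between cells were computed across the compared genes. Cell sex was read from Xist and from Ddx3y, Uty, Kdm5d and Eif2s3y.

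The lists and the naming rule were fixed before the data were examined. The rule names H19 and Igf2, the 12 largest differences in each direction whose mean and median have the same sign, and up to 4 members of each list with the largest differences. Sex-linked genes, predicted genes, clone names and pseudogenes were passed over, which removed 1 gene. To keep the text short, 2 members per list were carried into the alternatives, and 4 for the lists that stood apart. Adult genes named are H19, the 10 highest and the highest list members. Some genes that the rule names are not reported here. Neat1 was added after its values were seen.

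Departures from the plan were made after the files were opened. All cells were to be used, but wildtype cell 19 was left out. Its column was compared with the mean of the other cells in 29 stretches of 500 rows at offsets of up to 5 rows, and its best offset lay between -1 and 2 rows, differing from 0 in 24 stretches. The stretches began at row 25, so the 24 rows ahead of the alphabetical order were not checked in any cell. Across genes, the correlation of the differences with and without this cell was 0.954. The order of the rows was also checked, as were digit strings shared between cells of the same gene, requiring at least 5 identical significant digits at any decimal place, in both tables; values in exponent form were not compared. Alternatives tried were other pseudocounts of 0.1 and 10, rescaling to an equal total, shifting to an equal median, medians over cells, the ratio of mean RPKM, other filters, unmatched random lists, leaving out cells with few genes, and leaving out each cell in turn. Added after seeing the data were runs with wildtype cell 19, without the 24 rows placed ahead of the alphabetical order, with KO cells of enough detected genes, with cells of Xist under 1 RPKM, and without adult cells 23 and 24. Runs that changed the T1 cells applied the filter again to the cells used, so compared genes and list members differ between runs.

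The calculations were tested on simulated data. Values were drawn from normal distributions with each gene's mean and SD over the real cells, independently for each gene and cell. Such data hold no differences between cells in detected genes and no correlation between genes. The share of unchanged lists beyond the limits given here therefore need not hold for the real lists. Of 3867 genes, 200 were shifted by 2 on the log2 scale and recovered at a mean of 1.95 (SD 1.11), while the other genes had a mean of -0.01 (SD 1.10). Of 400 unchanged lists of 15 genes, 4% fell beyond the limits, and a shifted list reached percentile 100. A moved column was found in 29 of 29 stretches, and 100 of 100 planted digit copies were found against 0 in 1000 random pairs. Gene coordinates of the T1 comparison are from the GRCm38.p6 annotation. Software was Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.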

Results

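The series measured RNA in single mouse cells from the embryonic and adult blood stem cell lineage, with a stated focus on long non-coding RNAs. Of 53 samples, 48 were single-cell RNA libraries. They comprised 12 cells with a deleted form of the differentially methylated region (DMR) upstream of H19 (KO, numbered 1 to 12), 10 control cells that the labels call wildtype (numbered 13 to 22) and 26 adult haematopoietic stem cells (HSCs) from bone marrow. The KO and wildtype cells were T1 pre-HSCs, type 1 precursors of HSCs, sorted from the aorta-gonad-mesonephros region of E11 embryos, where the earliest HSCs arise. The other 5 samples were methylation libraries and were not analysed here. No embryo, litter or sorting day was named for any cell. Each group therefore counted as 1 sample, cells were not treated as replicates, and no test between genotypes was possible. Spreads given below are SDs or ranges over cells, and share intervals cover counting error only.

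The table of the T1 pre-HSCs listed 14833 genes in RPKM, and its sequencing depth was unknown. KO cells had a median of 3172 genes at 1 RPKM or more, with a range of 1517 to 8408. Wildtype cells had a median of 4176 and a range of 2067 to 5716. KO cells 2, 4, 5 and 6 had 5994, 6411, 8408 and 6215 genes, each more than any wildtype cell compared, while KO cells 1, 9 and 12 had 1517, 1891 and 1796, each fewer than any of them. The median of Actb, cytoplasmic actin, was 1285 RPKM in KO and 1371 RPKM in wildtype cells, and that of Rplp0, a ribosomal stalk protein, was 965 and 1057 RPKM. Mitochondrial genes took a median of 5.84% of the total in KO and 5.80% in wildtype cells. Wildtype cell 19 was left out, because its values were out of step with the gene rows in 24 of 29 stretches of 500 rows. Its median correlation with the mean of the other cells was 0.162 as deposited and 0.694 at the best offset, and Actb and Rplp0 were both listed at 0 there. The other 21 cells were in step in all 29 stretches, and the comparison of genotypes rests on these 12 KO and 9 wildtype cells. The stretches began at row 25. Whether any column is in step in the first 24 rows, which hold Spi1 and other transcription factors, was not checked.

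**Figure D1:**
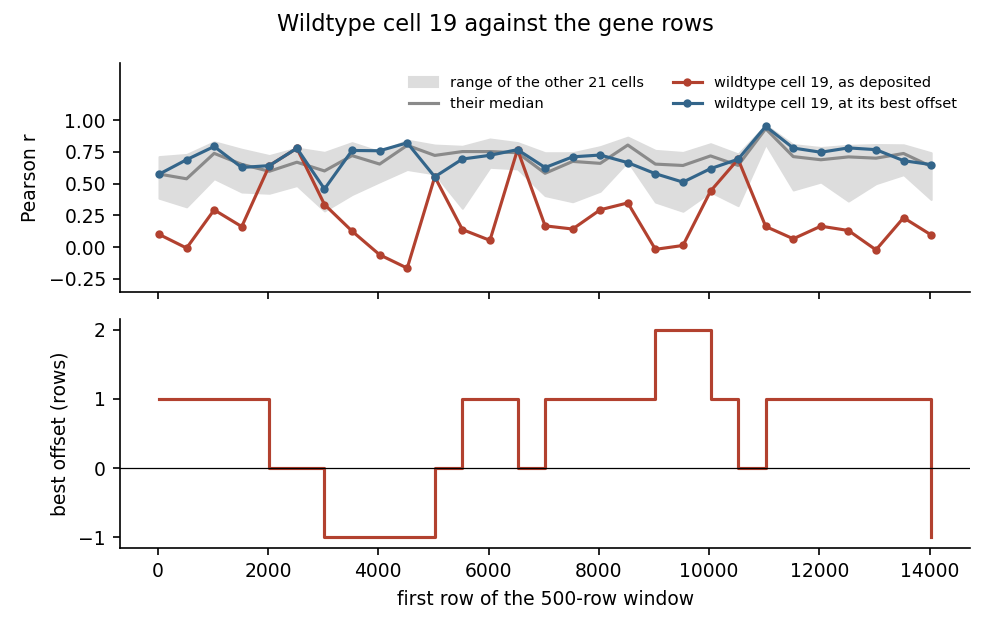
Pearson correlation of log2(RPKM + 1) with the mean of the other cells in successive stretches of 500 rows (top) and the row offset giving the highest correlation for wildtype cell 19 (bottom), both against the first row of each stretch. The red line of cell 19 as deposited lies at a median of 0.162, and the blue line at its best offset lies at a median of 0.694, within the reach of the other 21 cells (grey).

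The comparison of H19 DMR KO with wildtype cells asks how T1 pre-HSCs differ when the region controlling H19 is deleted. H19, an imprinted long non-coding RNA, lay far lower in KO than in wildtype cells, with no overlap between the groups. Its mean log2(RPKM + 1) was 4.30 ± 2.37 (SD over 12 cells) in KO and 9.08 ± 0.76 (SD over 9 cells) in wildtype cells, a difference of -4.78. H19 was still detected at 1 RPKM or more in 10 of 12 KO cells, 83.3% with an exact 95% interval of 51.6 to 97.9%. Igf2, the fetal growth factor gene next to H19 that responds to the same control region, was detected in all 12 KO and all 9 wildtype cells at overlapping levels.

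In KO cells 1 to 12, in order, H19 was at 10.2, 80.6, 28.9, 61.5, 3.86, 87.2, 27.4, 186, 0, 56.6, 0.81 and 7.29 RPKM. In wildtype cells 13 to 18 it was at 903, 389, 231, 592, 1261 and 847 RPKM, and in wildtype cells 20 to 22 at 477, 406 and 384 RPKM. The highest KO cell thus lay below the lowest wildtype cell. Igf2 had a mean log2(RPKM + 1) of 8.19 ± 1.68 in KO and 7.54 ± 2.40 in wildtype cells, a difference of 0.64 that is smaller than either SD. Igf2 spanned 15.0 to 1164 RPKM in KO and 1.49 to 516 RPKM in wildtype cells. Without wildtype cell 13, the lowest, the Igf2 difference was -0.14, and over cells with Xist under 1 RPKM it was -0.70. In the GRCm38.p6 annotation H19 lies on chromosome 7 at 142575530 to 142578146 and Igf2 at 142650768 to 142666816 of the same chromosome. The deposited table gives H19 as ENSMUSG00000000031.11 and Igf2 as ENSMUSG00000048583.12. How the deletion changes the H19 transcript itself cannot be read from gene-level values.

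**Figure D2:**
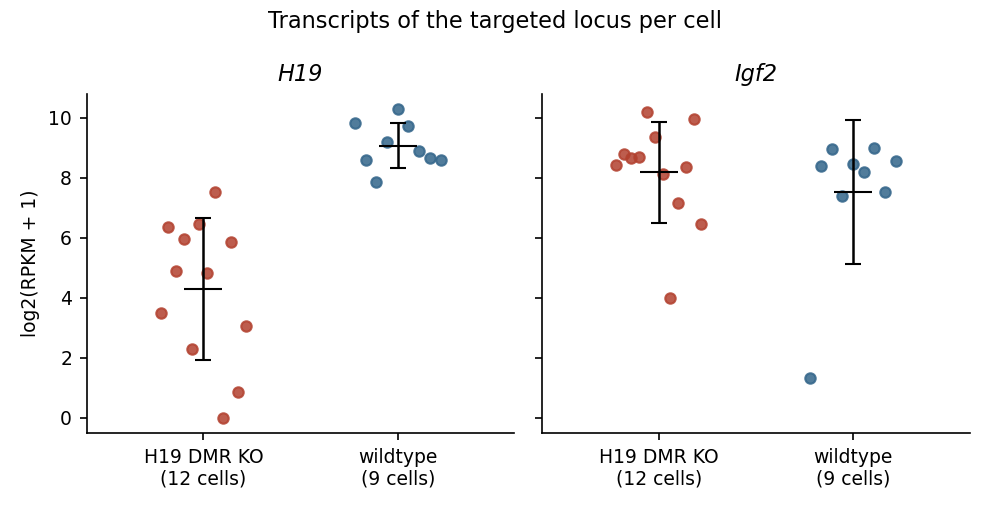
H19 and Igf2 in log2(RPKM + 1) for each of 12 KO cells (red) and 9 wildtype cells (blue); horizontal bars are group means and whiskers are 1 SD over cells. H19 lies at a mean of 4.30 in KO and 9.08 in wildtype cells without overlap, while the Igf2 levels overlap around means of 8.19 and 7.54.

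Across the 3867 genes detected in enough cells to be compared, the median difference, KO minus wildtype, was -0.36 on the log2(RPKM + 1) scale, with quartiles of -1.11 and 0.35. The SD of these differences over genes was 1.17, little above that of the unchanged genes in the simulated data. A place among the largest differences therefore does not by itself show an effect of genotype. Which of the genes named below differ by more than unchanged genes would was not tested. Of the genes named, Spi1 had the largest negative difference, larger in size than that of H19. It encodes PU.1, a master regulator of myeloid and lymphoid fate. Its row is among the 24 placed ahead of the alphabetical order, in which digit strings recur between cells. Spi1 was at 1 RPKM or more in 5 of 12 KO cells, with a maximum of 13.1 RPKM, and in 9 of 9 wildtype cells, with a minimum of 60.3 RPKM. Elof1, a transcription elongation factor, was detected in 4 of 12 KO and 7 of 9 wildtype cells, and Mtf2, an accessory subunit of the Polycomb repressive complex PRC2, in 5 of 12 and 8 of 9. Among genes higher in KO cells, Taf6, a subunit of the general transcription factor TFIID, was detected in 8 of 12 KO cells and listed at 0 in all 9 wildtype cells. Csnk1e, a casein kinase, was detected in 7 of 12 KO cells and in 0 of 9 wildtype cells, where its maximum was 0.472 RPKM.

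The differences of means on the log2(RPKM + 1) scale were -5.81 for Spi1, -4.12 for Elof1, -4.09 for Mtf2, -3.87 for Dnajc2, a ribosome-associated chaperone, and -3.70 for Papola, a poly(A) polymerase. Next came Ndufa3, a subunit of respiratory complex I, at -3.65, Bcap31, an endoplasmic reticulum protein, at -3.65, Ggnbp2 at -3.65, Sec11c, a signal peptidase subunit, at -3.63, Etv6, an ETS family repressor needed by HSCs, at -3.62, and Lyrm4, which takes part in iron-sulfur cluster assembly, at -3.61. Over all settings tried, Elof1 ranged from -7.77 to -0.96, Mtf2 from -7.50 to -2.39, Dnajc2 from -5.82 to -1.34 and Lyrm4 from -6.21 to -1.04. Etv6 was detected in 2 KO and 8 wildtype cells, and its value in KO cell 5 was blank. Spi1 and Etv6 stand among 24 rows placed ahead of the alphabetical order of the table, in which digit strings recur between cells as described under the transcription factors.

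In the other direction, Ddah2, an enzyme that clears methylated arginines, had a difference of 3.63, Coa7, an assembly factor of cytochrome c oxidase, one of 3.55, and the mitochondrial ribosomal proteins Mrpl48 and Mrpl53 of 3.55 and 3.53. Taf6 stood 3.48 above a group listed at 0, so no fold is given for it. Vbp1, a prefoldin subunit, differed by 3.48, Rps4l, a ribosomal protein paralogue, by 3.37, Csnk1e by 3.33, Uqcc2, an assembly factor of respiratory complex III, by 3.30, Anapc13, a subunit of the anaphase-promoting complex, by 3.24, Cdc123, an assembly factor of the translation initiation factor eIF2, by 3.03, and Rnaseh2a, a ribonuclease H2 subunit, by 2.90. Rps4l can share reads with its near-identical paralogues, so its value is uncertain. Most of these genes were detected in part of the cells only. Ddah2, for example, was at 1 RPKM or more in 8 of 12 KO and 4 of 9 wildtype cells, and Coa7 in 8 of 12 and 2 of 9. When each cell's values were shifted to an equal median, the median difference of all genes was 0.87, a shift of 1.24. With the 4 KO cells that reach the wildtype median of detected genes, the filter was applied again and left 7672 genes. Each of these cells had more detected genes than any wildtype cell compared, so many genes entered on their KO values. The median difference of this set was 1.28, which is not over the genes compared with all cells. With those 4 cells Ndufa3 lay higher in KO, at 0.92, as did Sec11c, at 1.17. Bcap31 fell to -0.031, Ggnbp2 to -0.18 and Papola to -0.53.

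Haematopoietic transcription factors lay lower in KO cells as a list, through its members in rows placed ahead of the alphabetical order. The 7 members in other rows had a median difference of 0.72, at percentile 97.8. Of 18 members compared, 13 were lower and 5 higher in KO cells, 11 by at least 1 on the log2 scale downwards and 3 upwards. The median difference was -1.91, at percentile 0 of 10000 random lists of the same size and expression, and with medians over cells the percentile was 11.6, within the limits. Besides Spi1 and Etv6, the members with the largest differences were Lyl1, a basic helix-loop-helix factor of early blood progenitors, and Ikzf2, an Ikaros family zinc finger protein. Lyl1 was detected in 3 of 12 KO and 7 of 9 wildtype cells, a difference of -3.39, and Ikzf2 in 1 of 12 and 7 of 9, a difference of -2.95. Spi1, Etv6, Lyl1 and Ikzf2 all stand in the rows ahead of the alphabetical order, in which digit strings recur between cells.

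The list divided by the place of its rows in the table. There, 24 genes precede the alphabetical order that all other rows follow apart from 39 steps. They include, besides the list members compared, Egr1, Hif1a, Sox7, Plagl1, Erg and Zfp37. Of all genes in these rows, in the list or not, 17 were compared and 15 were lower in KO cells. Their median difference was -1.97, at percentile 0. From outside the list, Egr1 and Hif1a were at -2.11 and -1.68, and Sox7 and Plagl1 at 1.22 and 2.56. The lower values were thus not limited to the list. The 11 list members among these rows, Runx1, Spi1, Gfi1, Tal1, Lyl1, Gata2, Fli1, Etv6, Meis1, Ikzf2 and Bcl11a, were all lower in KO cells, with a median difference of -2.57 at percentile 0. The 7 members in other rows had a median difference of 0.72 at percentile 97.8, and 2 of them were lower in KO cells, among them Mecom, a zinc finger gene of HSCs, at -0.61. The genes named from these rows, and the division by row, were chosen after their values were seen. Hoxa9, a homeobox gene of stem and progenitor cells, lay at 1.30, and Hhex, a homeobox gene needed for definitive blood formation, at 1.76.

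**Figure D3:**
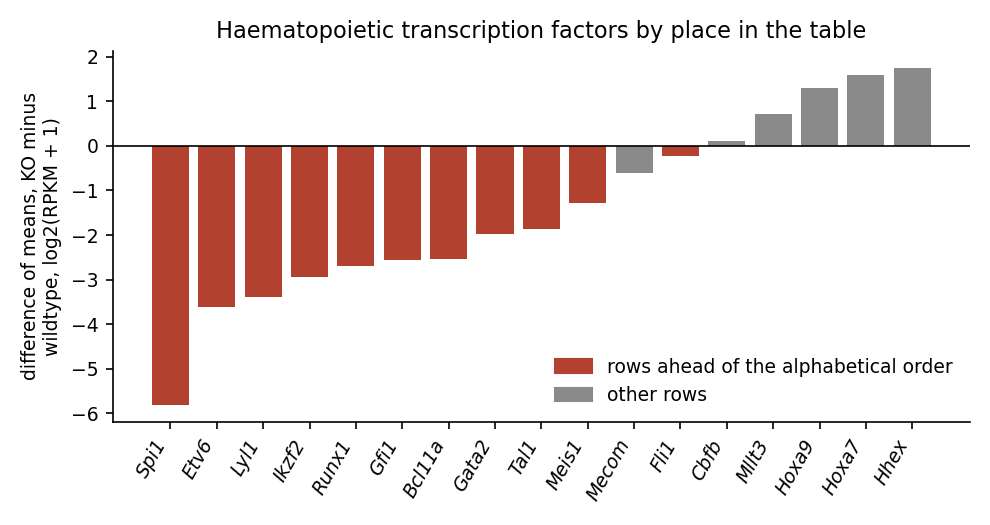
Difference of mean log2(RPKM + 1), KO minus wildtype, for 17 of the 18 haematopoietic transcription factors compared, coloured by whether the row stands ahead of the alphabetical order of the table (red, 11 genes) or among the other rows (grey, 6 genes). The red bars are all negative, and 5 of the 6 grey bars are positive; 1 member in other rows, lower in KO cells, is not shown.

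The same 24 rows differed from the rest of the table in their digits. Between cells of these rows, 12 pairs of values above 0 had identical significant digits, at least 5 of them and at any decimal place, in 9 genes: Bcl11a, Egr1, Gata2, Meis1, Hif1a, Ikzf2, Plagl1, Erg and Lyl1. All 12 pairs joined a KO with a wildtype cell, whereas 51.5% of the 2565 possible pairs in these rows did. Among 1060652 pairs in the other 14809 rows there were 0 such pairs. Egr1, for example, was listed at 7.3439 RPKM in KO cell 5 and 73.439 RPKM in wildtype cell 13, and at 14.2762 RPKM in both KO cell 11 and wildtype cell 16. A further 6 pairs shared only their last 4 digits, in Spi1, Sox7, Lyl1 and Zfp37, or 0.234% of pairs against 0.0109% in other rows. Spi1 was at 13.088 RPKM in KO cell 10 and 173.088 RPKM in wildtype cell 14, and at 12.945 RPKM in KO cell 12 and 152.945 RPKM in wildtype cell 13. H19 and Igf2 do not stand in these rows. Gfi1, a transcriptional repressor needed by HSCs, stands there too and was listed at 0 in all 12 KO cells but at 1 RPKM or more in 7 of 9 wildtype cells. These counts include wildtype cell 19, without which 11 pairs in 8 genes had identical digits and 5 pairs in 3 genes shared their last 4.

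Methyl donor and DNA methylation genes also lay lower in KO cells. Of 12 members compared, 10 were lower and 2 higher, with a median difference of -1.20 at percentile 1.21. Tdg, a thymine DNA glycosylase of active demethylation, was detected in 5 of 12 KO and 8 of 9 wildtype cells, a difference of -2.78, and Mbd3, a subunit of the NuRD complex, in 6 of 12 and 8 of 9, a difference of -2.71. Dnmt3a, a de novo DNA methyltransferase, had a difference of -2.42 and Ezh2, the histone methyltransferase of PRC2, one of -1.96. The percentile was 9.80 over cells with Xist under 1 RPKM, 7.64 with a filter at 5 RPKM and 4 with the KO cells that reach the wildtype median of detected genes, each outside the limit of 2.5. With those KO cells Dnmt3a lay higher in KO, at 1.41, and the difference of Mbd3 was about 0. The call also ended without any 1 of 8 single cells, as listed with the processing alternatives.

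Of 25 lists given a percentile, these 2 stood apart, both on the lower side, where chance alone would place 1.25 lists beyond the limits. The H19 locus and imprinted gene network had a median difference of -0.69 (percentile 21.2). Within it Cdkn1c, an imprinted cell cycle inhibitor, was detected in 9 of 12 KO and 9 of 9 wildtype cells. Plagl1, an imprinted zinc finger gene, was detected in 7 of 12 and 3 of 9, a difference of 2.56, and is among the rows with shared digits. Nnat, an imprinted membrane protein gene, was detected in 7 of 12 and 4 of 9, a difference of 2.30. Genes of pre-HSC and HSC surface and identity had a median of -0.70 (percentile 21.7), with Neurl3, a ubiquitin ligase gene marking haemogenic endothelium, at -2.13 and Emcn, an endothelial sialomucin, at 1.34 (0.18 with medians over cells). Neurl3 turned to 1.15 with the 4 KO cells that reach the wildtype median of detected genes and to 0.17 over cells with Xist under 1 RPKM. Long-term HSC genes had a median of -0.75 (percentile 19.3). Endothelial and arterial genes had a median of -0.32 (percentile 57.4), with Eng, a coreceptor of transforming growth factor beta, at -2.09 and Egfl7, a secreted endothelial factor, at -1.42. With those 4 KO cells Eng was at 1.37 and Egfl7 at 2.22, and over cells with Xist under 1 RPKM Egfl7 was at 0.047. Notch pathway genes had a median of 0.53 (percentile 91.9).

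Among cell cycle lists, S phase genes had a median difference of -0.17 (percentile 67.5), with Pcna, the replication clamp, at -3.19 and the replicative helicase subunit Mcm6 at -2.18. Without a filter the percentile was 1.25, and with the 4 KO cells that reach the wildtype median of detected genes Pcna was at 0.94 and Mcm6 at 0.49. G2 and M phase genes had a median of 0.51 (percentile 96.4), with the condensin subunit Smc4 at -2.22 (-0.074 with those 4 KO cells) and the mitotic kinase Cdk1 at 1.98, and the percentile was 97.7 with unmatched random lists and ranged from 8.54 to 99.64 without any 1 cell. Cell cycle inhibitors and quiescence genes had a median of -0.60 (percentile 43.2). In metabolism and translation, oxidative phosphorylation genes had a median of -0.64 (percentile 10.1), with 18 of 21 members lower in KO cells, among them Uqcrfs1, the Rieske protein of complex III, at -2.98. Uqcrfs1 was at 0.12 with those 4 KO cells, and without any 1 cell the percentile of the list ranged from 0.63 to 26.7, passing the limit without KO cell 6 or wildtype cell 13, 14 or 17. Glycolysis and oxygen response genes had a median of -0.23 (percentile 78.4) and ribosomal protein genes one of -0.19 (percentile 56.1).

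In signalling lists, insulin and IGF pathway genes had a median difference of -0.64 (percentile 39.1), let-7 target and fetal programme genes of -0.59 (percentile 37.2), transforming growth factor beta and BMP genes of 0.10 (percentile 86.8), and interferon and inflammatory signalling genes of -0.81 (percentile 13.7). Immediate early and heat shock genes had a median of -0.44 (percentile 48.0), with Dnajb1, an Hsp70 cochaperone, at -2.87 and Egr1, an immediate early factor in the rows with shared digits, at -2.11, and both at -0.35 with the 4 KO cells that reach the wildtype median of detected genes. Known long non-coding RNAs had a median of -0.42 (percentile 35.9), and with medians over cells the percentile was 1.41, beyond the limit. The list as fixed also held Trerf1, a protein-coding gene, at -2.25, and H19 itself, and no run left either out. After H19, the member with the largest difference was Snhg6, a snoRNA host gene, at 6 of 12 KO and 9 of 9 wildtype cells and a difference of -3.26, which turned to 0.32 over cells with Xist under 1 RPKM. With the 4 KO cells that reach the wildtype median of detected genes, the difference of Snhg6 was 1.02, and its mean over all cells was 429 RPKM in KO and 503 RPKM in wildtype cells. With those KO cells the list members and random lists came from the 7672 genes that passed the filter there. The percentile was then 99.95 for pre-HSC and HSC genes, 99.9 for endothelial and arterial genes, 99.8 for interferon genes and 0.04 for G2 and M phase genes. Over cells with Xist under 1 RPKM, that of G2 and M phase genes was 0.38.

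**Figure D4:**
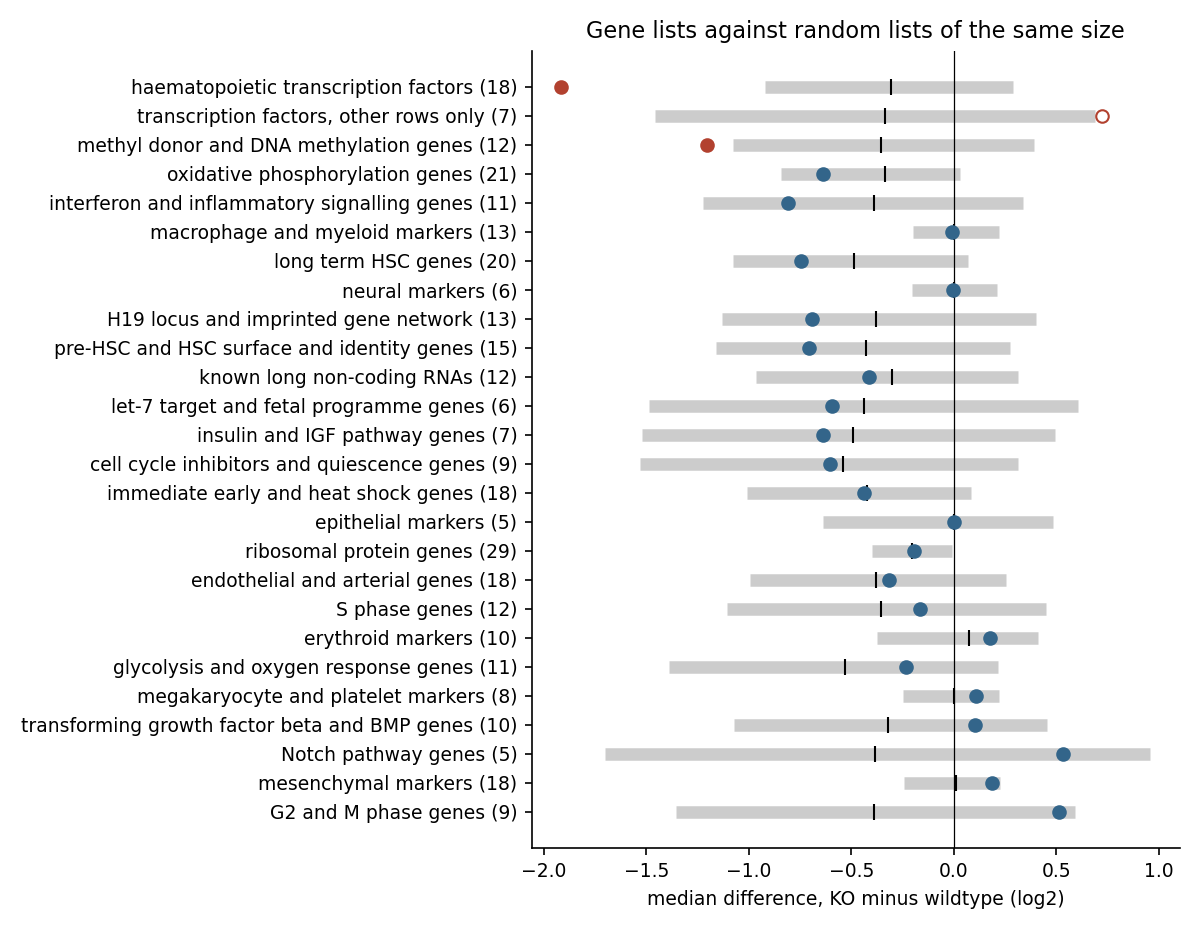
Median difference, KO minus wildtype, on the log2(RPKM + 1) scale for each gene list (circles, number of genes in parentheses), with the central 95% range (grey bars) and median (ticks) of 10000 random lists matched on size and expression. Lists beyond the limits are red: haematopoietic transcription factors at -1.91 and methyl donor and DNA methylation genes at -1.20, with the open circle at 0.72 for the 7 transcription factors in rows that follow the alphabetical order.

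No marker list of another cell type stood apart with all cells and the main settings. Erythroid markers had a median difference of 0.18 (percentile 70.2), with 7 of 10 members higher and 3 lower in KO cells. The adult globin Hba-a1 was detected in 2 of 12 KO and 0 of 9 wildtype cells. The adult globin Hbb-bt was detected in 0 of 12 KO and 3 of 9 wildtype cells, a difference of -1.22. Megakaryocyte and platelet markers had a median of 0.11 (percentile 84.8), macrophage and myeloid markers of -0.01 (percentile 19.2), neural markers of about 0 (percentile 20.0) and epithelial markers of 0 (percentile 52.5). Lyz2, the myeloid lysozyme, was detected in 6 of 12 KO and 6 of 9 wildtype cells, and Krt18, a simple epithelial keratin, in 7 of 12 and 7 of 9. Mesenchymal markers had a median of 0.18 (percentile 95.3), with 13 of 18 members higher and 5 lower in KO cells. The collagen gene Col1a1 was detected in 4 of 12 KO and 1 of 9 wildtype cells, and Col1a2 in 2 of 12 and 3 of 9. In KO cell 11 the mean of the mesenchymal markers was 4.85 in log2(RPKM + 1), while no other KO cell was above 1.55 and no wildtype cell above 2.39. The percentile of this list passed the limit with the ratio of mean RPKM (98.2), without cells of few detected genes (99.0) and without any 1 of 6 single cells, and that of megakaryocyte markers was 99.1 with the 4 KO cells that reach the wildtype median of detected genes. Lymphoid, mast and basophil, primordial germ cell, hepatic and sex-linked lists had fewer than 5 usable members and were given no percentile.

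At 1 RPKM or more, the genotypes differed in the sex-linked transcripts of their cells. Xist, the long non-coding RNA of the inactive X chromosome, was at 1 RPKM or more in 7 of 12 KO and 2 of 9 wildtype cells. Y-linked genes without Xist were detected in 2 of 12 KO and 6 of 9 wildtype cells, and both kinds together in 5 KO and 0 wildtype cells. Counting any value above 0, Xist was in 8 of 12 KO and 6 of 9 wildtype cells, and both kinds in 7 KO and 6 wildtype cells, so this difference depends on the threshold. Ddx3y can share reads with its X-linked counterpart Ddx3x, so a cell with both kinds is uncertain. Across genes, the median Spearman correlation between cells was 0.296 within KO, 0.396 within wildtype and 0.344 between the genotypes, so pairs from different genotypes were not less alike than pairs of KO cells. Genes are not independent replicates, and these correlations describe the cells only.

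The adult HSCs stand alone in the series as 1 group, and their table lists 6910 rows. Of the 2541 rows that match the reference annotation by name, 95.4% are long non-coding RNAs there. H19 was at 1 FPKM or more in 8 of 25 adult HSCs, 32% with an exact 95% interval of 14.9 to 53.5%, and its levels lay in separate ranges. The 8 cells spanned 88.6 to 1054 FPKM, and the other 17 cells lay at 0.514 FPKM or below. Gas5, a host of small nucleolar RNAs, was detected in 22 of 25 cells with a median of 318 FPKM, and Malat1, a nuclear speckle RNA, in 22 of 25 with a median of 61.0 FPKM. Tug1, a widely expressed long non-coding RNA, was detected in 18 of 25 cells with a median of 38.4 FPKM, and Neat1, the scaffold of paraspeckles, in 19 of 25 with a median of 26.3 FPKM. The imprinted Meg3 was detected in 14 of 25 cells with a median of 17.2 FPKM, Airn in 14 of 25 and Kcnq1ot1 in 11 of 25. The columns of adult cells 23 and 24 share digits. Of 325 genes compared between these 2 cells, 179 had identical significant digits, 87 at the same value and 92 at another decimal place, while the other 299 pairs of cells had 1 such match among 75153 pairs of values. Meg3, for example, was at 110.272 FPKM in cell 23 and 11027.2 FPKM in cell 24, and Airn at 0.747487 and 74.7487 FPKM. The values of the 2 columns are not independent, and all adult values given here include both. Without them H19 was detected in 7 of 23 cells and Meg3 in 12 of 23, where the median of Meg3 was 2.07 FPKM.

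Gm17275, an uncharacterised transcript, was among the 7 genes detected in all 25 cells and had the highest mean level, 7.67 ± 0.72 (SD over 25 cells) in log2(FPKM + 1), with a median of 236 FPKM. Adult cells had a median of 561 genes at 1 FPKM or more, with a range of 384 to 761. Of 4157 genes detected in at least 1 cell, 299 reached 1 FPKM in 50% or more of the cells. Xist was detected in 19 of 25 adult cells. The table was made separately and with another library method than that of the T1 pre-HSCs, so no level was set against theirs.

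**Figure D5:**
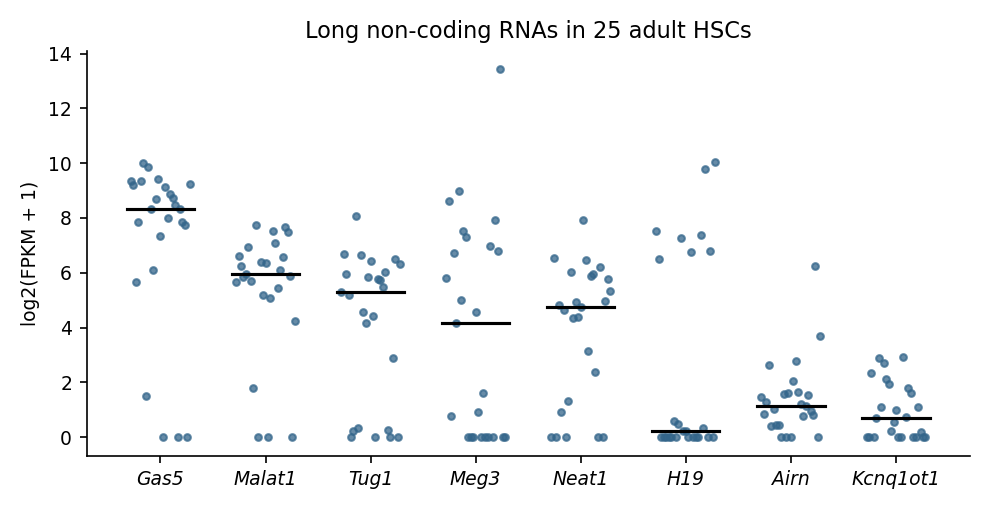
Levels of 8 long non-coding RNAs in log2(FPKM + 1) in each of 25 adult HSCs (points), with the median over cells (black lines). Gas5 has the highest median, 318 FPKM, and H19 shows 8 cells from 88.6 to 1054 FPKM above 17 cells at 0.514 FPKM or below.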

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

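The tests of row order and of shared digits, in both tables, were chosen only after the results they explain were seen. The tests of detected genes and of cell sex were written down before their results were seen. In the wildtype group, 18 of 104 sets of 9 values had 1 cell far from the others. The limit used lets chance pass 5.2 of them if values are normally distributed, which values with many zeros are not, so no excess is read from this count.

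In wildtype cell 13, Igf2 was low at 1.32 in log2(RPKM + 1), with the next cell at 7.41. The ribosomal protein gene Rpl7 was low there as well, at 6.32, and the mean of the epithelial markers was 0. In wildtype cell 14, the chaperone gene Dnajc2 was listed at 0, while Ddah2 was high at 6.84, Col1a1 at 5.55 and the mean of the mesenchymal markers at 2.39. In wildtype cell 15, Egr1 and Uqcrfs1 were listed at 0, Snhg6 was low at 2.79 and Emcn was high at 9.24. In wildtype cell 18, Coa7 was high at 4.67, and in wildtype cell 20 the adult beta-globin gene Hbb-bt was high at 7.71. In wildtype cell 22, Etv6 was low at 0.11, and Mrpl48, Vbp1, Cdk1 and the intermediate filament gene Nes were high at 5.50, 6.86, 4.70 and 2.5.

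The haematopoietic transcription factors lay lower in KO cells, at percentile 0 of random lists with means over cells, but at percentile 11.6, within the limits, with medians over cells. The tests below concern the values with means. For the list as deposited, whether a lower number of detected genes in KO cells played a part was not decided. The list stayed at percentile 0 with the 4 KO cells that reach the wildtype median of detected genes. Each of these had more genes than any wildtype cell compared, so detection was not matched. With all cells the 11 members ahead of the alphabetical order were at percentile 0. The run may therefore reflect those rows alone and does not speak for the other members. A different mix of cell sexes was not decided. The percentile was 0 over cells with Xist under 1 RPKM, but that limit does not equalise sex. Of those cells, 2 KO and 6 wildtype cells held a Y-linked gene at 1 RPKM or more, and 3 KO and 1 wildtype cell did not. The pattern went with the rows placed ahead of the alphabetical order, since the 7 members in other rows stood at percentile 97.8, the opposite side. Genotype, embryo, litter and processing day cannot be told apart, because no label ties cells to embryos.

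The recurring digits in those rows were set against 2 explanations. Chance matches are argued against by 46.8 same-digit pairs per 10000 pairs in these rows and 0 in the other 14809 rows. Values copied between whole columns would have brought such pairs to the other rows too, where 0 were found. Shared reads need not give identical digits after scaling to each cell's total, so this comparison cannot speak to them. What produced the digits stays open, and no biological explanation was tested.

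The methyl donor and DNA methylation list lay lower in KO cells at percentile 1.21, and technical explanations stayed open. The percentile was 4 with the 4 KO cells that reach the wildtype median of detected genes, and 9.80 over cells with Xist under 1 RPKM, in both cases between the bounds set beforehand. The number of detected genes and the mix of sexes therefore cannot be told apart from genotype for this list, since 4 and 5 KO cells remained in these runs. An effect of the deletion stays possible and untested.

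The columns of adult cells 23 and 24 had identical digits in 179 of 325 genes, or 55.1%, against 1 match among all other pairs of cells. What produced this was not tested and stays open.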

How the results depend on the processing

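The runs with wildtype cell 19, without the 24 rows ahead of the alphabetical order, with KO cells of enough detected genes and over cells with Xist under 1 RPKM, and without adult cells 23 and 24, were chosen only after the results were seen. No paired analysis was possible because the KO cells are numbered 1 to 12 and the wildtype cells 13 to 22, and the groups share no number. Depth is unknown, so what depth limits could not be measured. The H19 difference lay between -5.20 and -3.53 under all alternatives and between -5.07 and -4.39 without any 1 cell. Of 72 named differences, 37 had 1 sign under every setting. With wildtype cell 19 as deposited, none of the results carried into these runs reversed or crossed its limit.

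Except where the construction is named, the cause was not tested. After a shift to an equal median, differences were 0.019 for Hbb-bt, 0.21 for Col1a2, 0.18 for Mfng, 0.055 for Rheb and 0.19 for Bambi, where the main differences were negative. This shift moved the median of all genes by 1.24. With medians over cells, Col1a2 was at 0.045, the transcription factors were at percentile 11.6 and the known long non-coding RNAs at 1.41. With the ratio of mean RPKM, Ndufa3 was at 0.16, Rpl7 at 0.068 and the mesenchymal markers at percentile 98.2. Without cells of few detected genes, the mesenchymal markers were at percentile 99.0. Without a filter, S phase genes were at percentile 1.25. With a filter at 5 RPKM, the methylation list was at 7.64. With unmatched random lists, G2 and M phase genes were at 97.7. Without the 24 rows, the transcription factors were at 97.965, by construction from the 7 other members.

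With the 4 KO cells that reach the wildtype median of detected genes, the filter left 7672 genes, whose median lay 1.64 above the main median. The genes and list members compared were thus not those of the main run. The sign turned there for Ndufa3 (0.92), Sec11c (1.17), Lyz2 (2.38), Col1a1 (-0.62), Krt18 (0.56), Neurl3 (1.15), Eng (1.37), Egfl7 (2.22), Mfng (2.77), Pcna (0.94), Mcm6 (0.49), Cdkn1c (0.26), Dnmt3a (1.41), Rheb (1.02), Ccnd2 (1.23), Hmga1 (0.82), Bambi (0.93), Ifnar2 (0.39), Stat3 (1.91), Uqcrfs1 (0.12), Rpl18 (1.05), Rpl7 (0.57) and Snhg6 (1.02). Mbd3 (about 0), Bcap31 (-0.031) and Ggnbp2 (-0.18) lost their difference. Percentiles there were 99.1 for megakaryocyte markers, 99.95 for pre-HSC genes, 99.9 for endothelial genes, 0.04 for G2 and M phase genes, 4 for the methylation list and 99.8 for interferon genes. With the 9 KO cells that reach the lowest wildtype cell, Mfng was at 0.13 and Rpl7 at 0.15.

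Over cells with Xist under 1 RPKM, 5 KO and 7 wildtype, differences were 0.18 for Lyz2, 0.17 for Neurl3, 0.047 for Egfl7, 1.11 for Mfng, 1.33 for Rheb, 0.72 for Ccnd2, 0.70 for Rpl18 and 0.32 for Snhg6. G2 and M phase genes were at percentile 0.38 and the methylation list at 9.80. Counting any value above 0, Xist was found in 8 KO and 6 wildtype cells, Y-linked genes without Xist in 4 KO and 3 wildtype cells, and both kinds in 7 KO and 6 wildtype cells.

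Without any 1 cell, percentiles ranged from 8.16 to 99.24 for mesenchymal markers, 8.54 to 99.64 for G2 and M phase genes, 0.13 to 8.03 for the methylation list and 0.63 to 26.7 for oxidative phosphorylation genes. The methylation list left its limit without KO cell 7 (8.03), 8 (5.17), 10 (2.58) or 12 (2.93), or wildtype cell 13 (4.29), 14 (7.58), 15 (3.28) or 17 (6.46). G2 and M phase genes passed it without KO cell 2, 4 or 10, oxidative phosphorylation genes without KO cell 6 or wildtype cell 13, 14 or 17, and mesenchymal markers without KO cell 2, 7, 8 or 10 or wildtype cell 14 or 20. The transcription factors kept their side without any 1 cell.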

Other observations

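Counting which adult HSCs held H19 and Meg3 together and comparing their digits were chosen only after their values were seen. In adult HSCs, the imprinted long non-coding RNA Meg3 was found both in cells with and in cells without H19. It was at 1 FPKM or more in 5 of the 8 cells with H19 and in 9 of the 17 cells without it. Where detected, H19 had a median of 160 FPKM. In adult cell 24, Meg3 stood at 11027 FPKM, while the next cell was at 506 FPKM. This value made up 29.2% of the total of that cell, 37739 FPKM, where the next highest total was 13107 FPKM, that of cell 23. The digits of this Meg3 value are those of cell 23, at 110.272 FPKM, and the 2 columns share digits in 179 genes.

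The number of detected genes varied more among KO than among wildtype cells. It ranged from 1517 to 8408 in KO cells and from 2067 to 5716 in wildtype cells. KO cell 5, with 8408 genes, had H19 at 3.86 RPKM, and KO cell 1, with 1517 genes, had H19 at 10.2 RPKM. KO cell 9, with 1891 genes, had H19 listed at 0, and KO cell 12, with 1796 genes, had it at 7.29 RPKM. In KO cells 2, 4 and 6, with 5994, 6411 and 6215 genes, H19 was at 80.6, 61.5 and 87.2 RPKM. Whether H19 follows the number of detected genes among KO cells was not tested.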
